A study of Caenorhabditis elegans with 4 samples.

How the data were processed

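ChIP-seq for DPY-26 was performed in mixed-stage N2 embryos grown at 20 °C, with a rabbit polyclonal antibody raised against part of the protein. Per the labels' protocols, live embryos were fixed in 2% formaldehyde for 30 minutes, chromatin was sheared by sonication, 2 mg of extract entered each immunoprecipitation and 10% was kept as input DNA. The series has 2 ChIP and 2 input libraries. The labels number the replicates of both.

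The values used were the start, end and score of each peak. Reads were aligned with BWA to the ce10 genome, per the submitters' processing notes, which give no version. The peaks were called with MACS in the 2 replicate lists and with MACS v2 in the series-level list, per the file headers and the source column of the files. The file headers name WormBase release WS220 as the genome build. The score per peak is the authors' own value from their peak caller, and its scale is not given in the sources used here. The deposited scores start at 50 in the replicate lists and at 1.30 in the series-level list, so they were compared only within a list. Whether input libraries served as the control in peak calling, which filters were used and whether the series-level list came from pooled replicates are not given in the sources used here. Because the caller differed between replicate and series-level lists, peak numbers and widths of these lists are not on one scale.

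Samples were grouped by their titles. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Chromosome lengths were taken as the largest peak end found on each chromosome in any list. They stand in for the WS220 lengths, which were not used here, and can be too short where the last peak lies inside the chromosome or too long where a peak was extended past its end. The build was taken from the file headers and was not checked against chromosome lengths. The 6 mitochondrial peaks of the series-level list were left out of the comparisons. For X against autosomes, peak midpoints were counted in 1 Mb bins, keeping a last bin only if it reached 50% of that length, and bin densities were compared by a two-sided permutation test with 100000 permutations. Where at most 100000 arrangements existed, all were enumerated. The share of peaks on the X was compared with its share of length by an exact binomial test, with Wilson 95% intervals. Medians of score and width were compared by permuting peaks. Overlap between lists required 1 bp and was tested against 1000 circular shifts within each chromosome, one-sided, and X and autosomal overlap were compared by Fisher's exact test. The overlap counts were checked against bedtools 2.31.1, which gave the same 1194 peaks at 1 bp. With 2 ChIP libraries no exact or permutation test over libraries can reach 0.05, so p-values describe bins or peaks within a list. They do not measure variation between cultures.

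The tests were run on simulated lists first. With no X excess, 9 of 100 simulated lists the size of replicate 1 (1463 peaks) passed 0.05 in the bin test, and with a 2-fold excess all 100 did, with a mean estimate of 2.01. For the shift test on lists of 400 peaks, 2 of 100 independent pairs and 100 of 100 pairs that shared 20% of positions passed. The shift lists held the X at its share of length, so peaks as dense as on the real X were not simulated. Fewer permutations and shifts were drawn per simulated list than in the analyses. The 9 in 100 rate is above the nominal 5 in 100.

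Regions named in the text followed a rule fixed before the data were examined. The rule takes the 10 highest-scoring X peaks and the 10 highest-scoring autosomal peaks of the series-level list that overlap both replicate lists, plus the highest-scoring peak of each chromosome. Planned comparisons of promoters and of gene lists were not run, because the gene table at hand was for the WBcel235 assembly and coordinates of different builds were not mixed. Alternatives covered score cuts, merging of peaks within 500 bp, base pairs covered, other bin sizes, stricter overlap, lists of equal length and each replicate alone.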

Results

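Binding of DPY-26 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2. DPY-26 is a subunit of condensin, the ring-shaped complex that compacts chromosomes. It belongs both to condensin I and to the condensin of the dosage compensation complex, which lowers transcription from the X chromosomes of hermaphrodites. The series holds 4 samples, 2 ChIP libraries and 2 input DNA libraries. Peak lists of the 2 ChIP libraries and 1 series-level peak list were analysed, and no peak list of the input libraries was used here. Replicate 1 listed 1463 peaks, replicate 2 listed 2671 peaks and the series-level list held 9882 peaks. The lists give no read counts, so the sequencing depth behind each peak is unknown. Nothing in the labels says whether the ChIP replicates came from separate cultures. Coordinates are on WormBase WS220 as the file headers state. No chromosome lengths of that release were used here, so the build was not checked, and whether the last peaks of each chromosome end within it is open. Peaks are named by position because no gene annotation of that release was used here.

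The first comparison asked how DPY-26 peaks were distributed between the X chromosome and the 5 autosomes. DPY-26 peaks lay overwhelmingly on the X chromosome in both replicates and in the series-level list. The X held 1235 of 1463 peaks in replicate 1, which is 84.4% with a Wilson 95% interval of 82.5% to 86.2%. In replicate 2 it held 2542 of 2671 peaks, or 95.2% with an interval of 94.3% to 95.9%. In the series-level list it held 9008 of the 9876 nuclear peaks, or 91.2% with an interval of 90.6% to 91.8%. The X makes up 17.7% of the nuclear chromosome length spanned by the peaks, and the exact binomial test against that share gave a p-value below the smallest number the software can represent in all 3 lists. These intervals treat peaks as independent and cover counting error only.

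Every 1 Mb bin of the X had a higher peak density than any autosomal bin, in all 3 lists. In replicate 1 the X carried 69.4 ± 13.1 peaks per Mb (SD over 18 bins) and the autosomes 2.76 ± 2.20 (SD over 82 bins), a ratio of 25.1. The lowest X bin held 44 peaks per Mb and the highest autosomal bin held 11. In replicate 2 the X carried 143.4 ± 13.3 peaks per Mb and the autosomes 1.58 ± 1.70, a ratio of 90.6, with a lowest X bin of 121 and a highest autosomal bin of 10. In the series-level list the X carried 508 ± 53.5 peaks per Mb and the autosomes 10.5 ± 5.05, a ratio of 48.4, with a lowest X bin of 352 and a highest autosomal bin of 28. The two-sided permutation test of bin densities gave p = 1e-05 in each of the 3 lists, the smallest value that 100000 permutations can give. Among the 1194 replicate 1 peaks that overlapped a replicate 2 peak, the ratio was 97.2 with the same p of 1e-05. The overlap filter itself favours the X, since circular shifts of replicate 1 gave 49.9% overlap on the X and 0.514% on the autosomes. The rise from 25.1 to 97.2 therefore does not measure agreement of sites.

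Peak densities of the autosomes lay close together. In replicate 1 they ranged from 2.45 peaks per Mb on chromosome I to 3.06 on chromosome V, against 69.7 on the X. In replicate 2 they ranged from 1.24 on chromosome V to 2.10 on chromosome III, against 143.5 on the X. In the series-level list they ranged from 9.22 on chromosome V to 12.3 on chromosome III, against 508 on the X. With 6 chromosomes an exact permutation test cannot give a p below 0.167, and it gave 0.167 in each list. Peaks covered 3.93% of the X in replicate 1, 43.1% in replicate 2 and 20.4% in the series-level list, while no autosome was covered beyond 0.422% in any list. The size of the ratio depended on the measure. By base pairs covered it was lower in replicate 1, at 12.6, but higher in replicate 2, at 126.2, and in the series-level list, at 59.3. Among the highest-scoring 25% of each list it was 88.8 in replicate 1, 511 in replicate 2 and 84.8 in the series-level list.

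**Figure D1:**
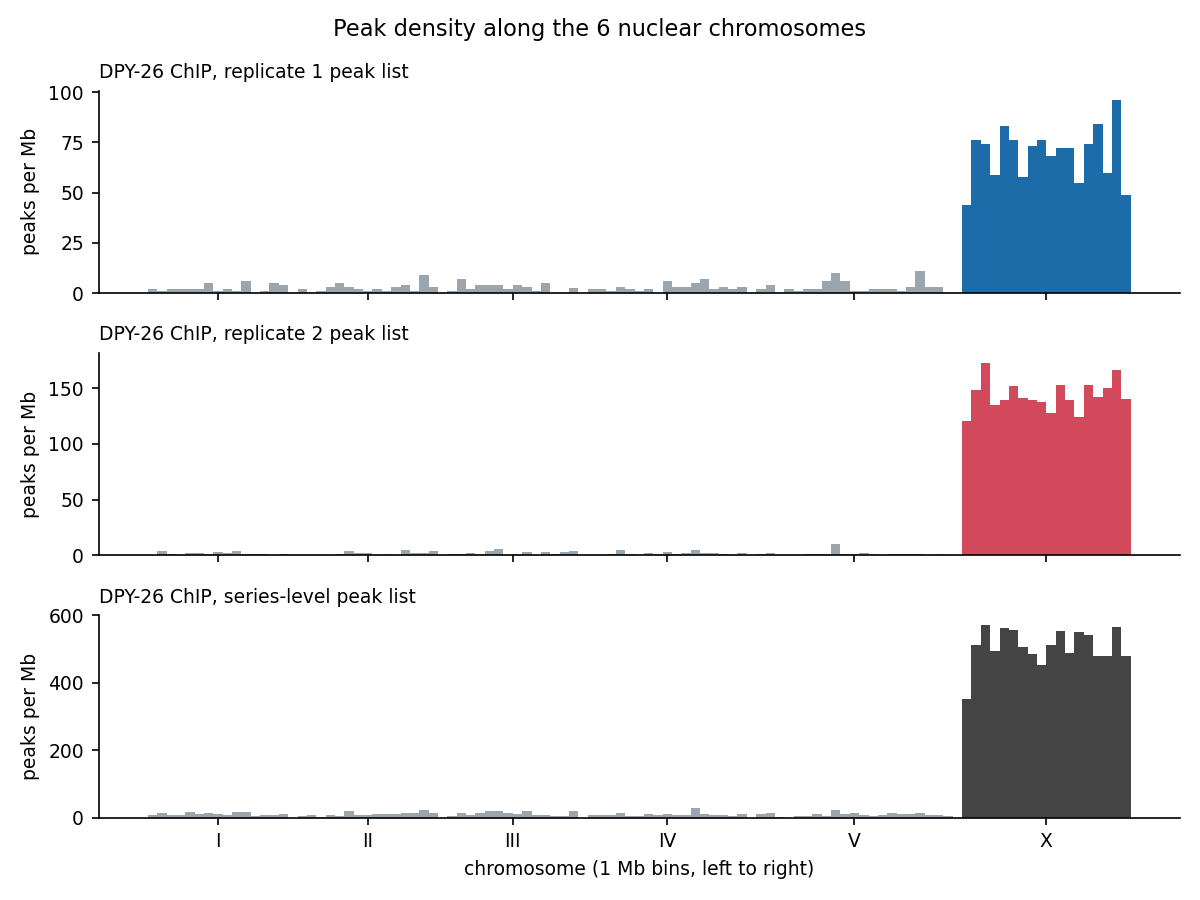
Peaks per Mb in 1 Mb bins (vertical axis) along the 6 nuclear chromosomes (horizontal axis) for the 3 peak lists, with the X in colour or black and the autosomes in grey. The X bins lie between 44 and 96 peaks per Mb in replicate 1, between 121 and 173 in replicate 2 and between 352 and 572 in the series-level list, above all autosomal bins of the same list.

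X peaks also scored higher than autosomal peaks within each list. The scores are the authors' values and were compared only within a list. In replicate 1 the median score was 162 on the X (quartiles 86.4 and 343.6) and 100.3 on the autosomes (quartiles 73.6 and 171.4). In replicate 2 the medians were 215 on the X (quartiles 103.1 and 517.6) and 101.8 on the autosomes (quartiles 73.4 and 154.0). In the series-level list they were 7.10 on the X and 6.38 on the autosomes. Two-sided permutation tests of the median difference, adjusted by Benjamini-Hochberg over the 6 tests of score and width, gave p = 0.000220, 0.00159 and 0.00566 for the 3 lists in that order. The series-level difference was no longer past the threshold without the highest-scoring 5% of peaks (permutation test, unadjusted p = 0.185). These tests treat peaks as independent.

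Widths did not differ in a common direction. X peaks were narrower than autosomal peaks in replicate 1, with medians of 488 bp and 629 bp (adjusted p = 3.00e-05, permutation test). They were wider in replicate 2, with medians of 2317 bp and 1884 bp (adjusted permutation p = 0.00378), and in the series-level list, with medians of 312 bp and 233 bp (adjusted permutation p = 3.00e-05).

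The strongest sites were broad X regions, found in both replicates and lying between 805293 and 17546511. Among series-level peaks that overlapped a peak of each replicate, 6 X peaks shared the highest score of the list, 226.42. They lay on the X at 2994404 to 2998844, 6295074 to 6298837, 8032218 to 8041694, 9463232 to 9469319, 11934279 to 11939112 and 13698184 to 13704295. Their widths ran from 3764 bp to 9477 bp, against a median of 303 bp for the list. The other X peaks among the highest 10 lay at 16054880 to 16057995 with a score of 225.76, at 1343488 to 1346272 and 17542914 to 17546511 with 220.08 each, and at 805293 to 809566 with 218.95. In replicate 2 all 10 of these regions overlapped a peak at the score of 3100, and so did 9 of them in replicate 1. The exception was the region starting at 1343488, which scored 2692.7 in replicate 1 and ranked 21 there. The value 3100 recurred exactly in 17 peaks of replicate 1 and 30 peaks of replicate 2, so the order among these sites cannot be read from the replicate lists.

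The replicated autosomal peaks with the highest series-level scores were narrower and ranked well below the X sites. The highest autosomal peak of the series-level list lay on chromosome I at 8224233 to 8224661. Its score of 45.82 gave it rank 686, and it scored 369.34 in replicate 1 and 177.1 in replicate 2. The highest peaks of the other autosomes lay on chromosome II at 11960580 to 11961030 (score 44.94), chromosome III at 10461051 to 10461392 (score 44.09), chromosome IV at 11025871 to 11026438 (score 41.83) and chromosome V at 15873763 to 15874140 (score 37.42). Each overlapped a peak in both replicates. The remaining members of the highest 10 lay on chromosome V at 8500351 to 8500696, 19642951 to 19643327, 11313973 to 11314423 and 12001862 to 12002308, and on chromosome I at 8259396 to 8259698, with scores from 27.58 to 34.62. All 10 were between 303 bp and 568 bp wide in the series-level list. This order is that of the series-level scores and did not hold in the replicate lists. The chromosome III peak scored 94.66 in replicate 1 and 100.35 in replicate 2, below the autosomal medians of 100.31 and 101.77. A wider replicate 1 peak of 2646 bp, on chromosome I at 10130536 to 10133181, scored 1009.41. Its replicate 2 partner scored 294.79, but its series-level score was 10.84.

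**Figure D2:**
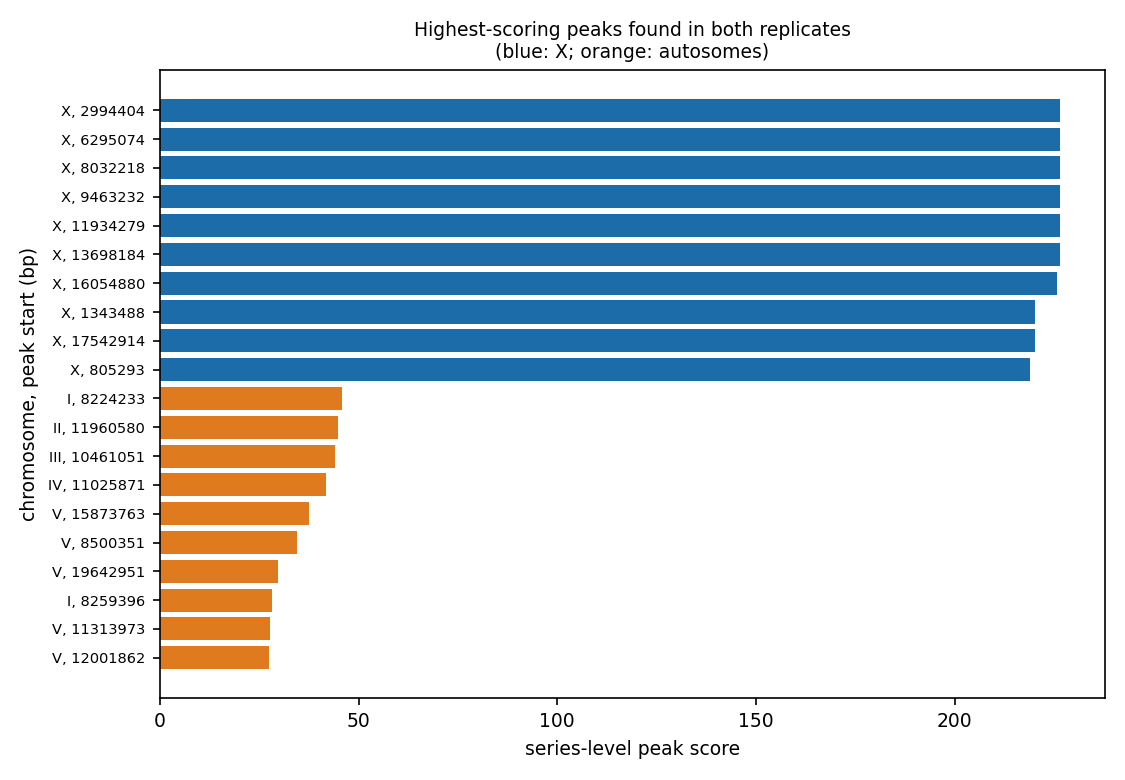
Series-level peak score (horizontal axis) of the 10 highest-scoring X peaks and the 10 highest-scoring autosomal peaks that overlap a peak in both replicates, labelled by chromosome and start (vertical axis). X bars lie between 218.95 and 226.42 and autosomal bars between 27.58 and 45.82.

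The next comparison asked how far the ChIP replicates located the same sites. On the X, 1140 of 1235 replicate 1 peaks (92.3%, Wilson 95% interval 90.7% to 93.7%) overlapped a replicate 2 peak by at least 1 bp. Circular shifts of the list along the chromosome gave 49.9% on average, because replicate 2 peaks covered 43.1% of the X, so the observed share was 1.85 times chance. On the autosomes 54 of 228 replicate 1 peaks (23.7%, interval 18.6% to 29.6%) overlapped a replicate 2 peak, against 0.514% under shifts, which is 46.0 times chance. The folds of X and autosomes are not comparable, because a chance level of 49.9% leaves the X fold little room above 1.85. In the other direction, 904 of 2542 X peaks of replicate 2 (35.6%) and 50 of 129 autosomal peaks (38.8%) overlapped a replicate 1 peak, against 20.7% and 0.851% under shifts. The one-sided permutation test against 1000 circular shifts gave p = 0.001 for each of the 4 shares, the smallest value it can give.

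A replicate 1 peak was more often matched in replicate 2 when it lay on the X than when it lay on an autosome, with an odds ratio of 38.7 (Fisher's exact test, two-sided, p = 2.85e-105). The share expected by chance also differed between X and autosomes, as given above, and the Fisher test does not account for this. For replicate 2 peaks the odds ratio was 0.872 (Fisher's exact test, two-sided, p = 0.453). Both odds ratios depended on the overlap rule and on peak width. With replicate 2 peaks resized to the replicate 1 median of 498 bp, a choice made after seeing the data, 46.1% of X peaks and 18.9% of autosomal peaks of replicate 1 were matched, and the odds ratio fell to 3.68 (Fisher's exact test, two-sided, p = 2.01e-15). The shares in replicate 2 were then 22.03% of X peaks and 32.6% of autosomal peaks, an odds ratio of 0.585 that passed the threshold (Fisher's exact test, two-sided, p = 0.00683). With 50% reciprocal overlap, 0.243% of X peaks and 3.95% of autosomal peaks of replicate 1 were matched, the X share lay below its shifted value of 1.15%, and the odds ratio turned to 0.0593 (Fisher's exact test, two-sided, p = 6.73e-06). Peak widths set this last outcome. Of the replicate 1 peaks matched at 1 bp, 3 of 1140 on the X and 9 of 54 on the autosomes met a replicate 2 peak within a factor of 2 of their own width, which the reciprocal rule needs, and all of these passed it. Replicate 2 was also reduced to its 1463 highest-scoring peaks, the number in replicate 1, which left it 27 autosomal peaks. On the autosomes 22 of 228 peaks of replicate 1 (9.65%) and 20 of 27 of replicate 2 (74.1%) were then matched. The few autosomal peaks left in replicate 2 limit the replicate 1 share, so these 2 shares mainly reflect list sizes. On the X 86.0% and 58.1% were matched.

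Peak widths set the replicates apart. The median width was 498 bp in replicate 1 (quartiles 371 bp and 652 bp) and 2299 bp in replicate 2 (quartiles 1648 bp and 3434 bp), a ratio of 4.62 with a bootstrap 95% interval of 4.42 to 4.78 over peaks. The narrowest peak was 150 bp in replicate 1 and 998 bp in replicate 2. Series-level peaks had a median of 303 bp, but they came from another caller version, so this width is not on one scale with the replicates.

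**Figure D3:**
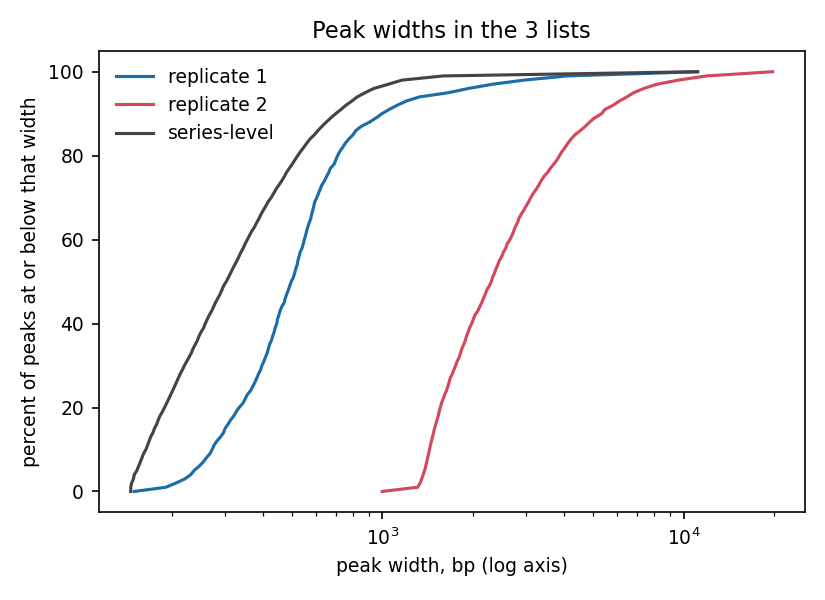
Percent of peaks (vertical axis) at or below each width in bp (horizontal log axis) for the 3 peak lists. The replicate 2 curve starts at 998 bp and passes its median at 2299 bp, to the right of the replicate 1 median of 498 bp and the series-level median of 303 bp. The series-level list came from another caller version, so its widths are not on one scale with the replicates.

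Peaks matched one to one between the replicates ranked similarly on the X. The one-to-one rule kept 744 of the 1140 replicate 1 X peaks matched at 1 bp. The highest replicate 1 score among these pairs was 2895.81, so the 17 replicate 1 peaks at 3100 were not covered. Across the 744 X pairs Spearman's rho of the scores was 0.70 and Pearson's r of the log2 scores was 0.70, each with a Benjamini-Hochberg adjusted permutation p of 2.00e-05 over 4 tests. Across the 46 autosomal pairs rho was 0.35 (adjusted permutation p = 0.0236) and r was 0.33 (adjusted permutation p = 0.0262). Over the 9 autosomal pairs with 50% reciprocal overlap rho was 0.80 (exact permutation test, unadjusted p = 0.0138), while r was 0.484 and no longer past the threshold (exact permutation test, unadjusted p = 0.197). These correlations run across peaks, which are not independent replicates, and the difference between X and autosomes was not tested.

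**Figure D4:**
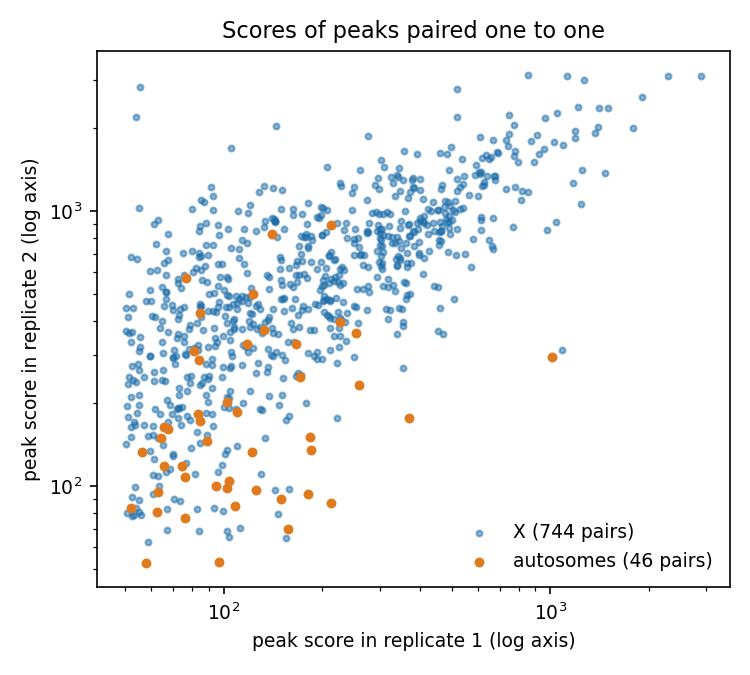
Peak score in replicate 2 (vertical log axis) against the score in replicate 1 (horizontal log axis) for peaks that overlap one to one, with 744 X pairs in blue and 46 autosomal pairs in orange. Each point is 1 pair of peaks, and the X pairs show the rising trend that Spearman's rho of 0.70 describes.

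The series-level list held many X peaks that replicate 1 lacked. It came from another caller version and held more peaks, so an unmatched peak need not reflect a difference in signal. Of its 9008 X peaks, 1094 (12.1%) overlapped peaks of both replicates, 88 (0.977%) overlapped replicate 1 alone, 5077 (56.4%) overlapped replicate 2 alone and 2749 (30.5%) overlapped neither. X peaks found in both replicates had a median series-level score of 51.1, against 5.07 for those found in neither. Of the 868 autosomal peaks, 78 (8.99%) overlapped both replicates, 142 (16.4%) replicate 1 alone, 109 (12.6%) replicate 2 alone and 539 (62.1%) neither. Conversely, 99.5% of X peaks of replicate 1 and 99.6% of X peaks of replicate 2 overlapped a series-level peak, compared with 67.1% and 91.5% of their autosomal peaks. Because X peaks are dense, circular shifts, added after these shares had been seen, already gave 42.9% and 80.7% on the X but 1.37% and 2.28% on the autosomes. Likewise, 68.5% of series-level X peaks overlapped any replicate 2 peak, against 48.03% under shifts. The series-level list is not independent of the replicates, and how it was made is not given in the sources used here.

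The last comparison asked whether peaks were more frequent in the central 50% of a chromosome or in its outer parts. On the X, no list showed a difference past the threshold. The centre carried 70.3 ± 8.87 peaks per Mb and the outer parts 68.4 ± 16.8 in replicate 1 (SD, 9 bins each, exact permutation test, adjusted p = 0.772). The X densities were 139.2 ± 9.46 and 147.6 ± 15.7 in replicate 2 (exact permutation test, adjusted p = 0.387), and 519 ± 39.05 and 497 ± 65.5 in the series-level list (exact permutation test, adjusted p = 0.528). On the autosomes the series-level list carried 12.0 ± 5.29 peaks per Mb in the centres and 8.96 ± 4.33 in the outer parts (SD, 41 bins each), a ratio of 1.34 (permutation test within chromosomes, two-sided, adjusted p = 0.0299 over 6 tests). The ratios in the replicates were 1.17 and 1.46, with adjusted permutation p of 0.528 and 0.365. The series-level call was lost when base pairs covered replaced peak numbers (ratio 1.30, permutation test, unadjusted p = 0.11).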

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

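The series-level list held 6 peaks on mitochondrial DNA, which no comparison used. They were singled out as signal in data outside the comparisons, with 6 peaks against the 3 counts that a count of 0 allows. Both replicate lists held 0, but those lists are shorter and came from another caller version, and the 6 peaks rank only 7053 to 9692 of 9882, so their absence there is not informative. The highest mitochondrial score was 4.65, at 8563 to 9136 of the mitochondrial genome, below the list median of 7.02.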

How the results depend on the processing

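The X excess over the autosomes kept its direction and its side of the threshold in all 3 lists under every alternative run, with density ratios from 12.6 to 88.8 in replicate 1, 72.9 to 511 in replicate 2 and 39.9 to 84.8 in the series-level list. For the peaks shared by both replicates (ratio 97.2), using one list alone gave 25.1 to 90.6, the lower value being replicate 1 alone. The overlap filter favours X peaks by chance alone, so 97.2 does not isolate the X excess of replicated sites. The alternatives not named here kept direction and side, except that the autosomal centre ratio of replicate 2 was exactly 1 in its highest-scoring 25%. Score agreement at 50% reciprocal overlap had too few pairs on the X, and over 9 autosomal pairs r was 0.484, no longer past the threshold (exact permutation p = 0.197), and rho 0.80; the alternatives for promoters and gene lists were not run. With 50% reciprocal overlap the matched share of all peaks and of X peaks fell to the level of shifted lists or below: 0.820% of all and 0.243% of X peaks of replicate 1, and 0.449% of all and 0.118% of X peaks of replicate 2. On the autosomes it stayed above shifted lists, at 3.95% against 0.0671% in replicate 1 and 6.98% against 0.124% in replicate 2 (permutation p = 0.001 each). The odds ratio of overlap became 0.0593 for replicate 1 and 0.0158 for replicate 2 (Fisher's exact p = 6.73e-06 and 2.12e-10). Widths set these values, since only 3 X and 9 autosomal peaks of each replicate met a peak within a factor of 2 of their width, and all of these passed the rule. With replicate 2 peaks resized, chosen after seeing the data, the odds ratio was 3.68 for replicate 1 and 0.585 for replicate 2, now past the threshold (Fisher's exact p = 0.00683). Other overlap rules left the shares above those of shifted lists (permutation p = 0.001) but moved them. With replicate 2 cut to the length of replicate 1, 9.65% of the 228 autosomal peaks of replicate 1 were matched. In replicate 2 these were 58.1% of X peaks and 74.1% of the 27 autosomal peaks left. With midpoints within 500 bp, 45.9% of X peaks of replicate 1 and 22.1% of replicate 2 were matched. In the highest-scoring 50% of each list it was 13.04% of autosomal peaks of replicate 1, where the odds ratio of replicate 1 was 76.7. Requiring 50% of the series-level peak to be covered put 9.39% of all and 9.47% of X peaks in both replicates, 54.7% of all and 58.8% of X peaks in replicate 2 alone and 0.777% of X peaks in replicate 1 alone. The series-level score difference shrank to 0.335 without the highest-scoring 5%, and the autosomal centre ratio of the series-level list lost its call by base pairs covered (1.30). Centre-to-outer ratios that had not passed the threshold changed direction in these cases: on the autosomes, 0.80 in replicate 1 (highest-scoring 25%) and 0.976 in replicate 2 (highest-scoring 50%); on the X, 1.02 (highest-scoring 25%) and 1.06 (base pairs covered) in replicate 2, and 0.982, 0.931 and 0.976 in the series-level list (highest-scoring 50%, highest-scoring 25%, 3 equal parts). The autosomal ratio of replicate 2 rose to 1.81 with 3 equal parts, now past the threshold; the cause was not tested. Read depth is unknown, so its effect on peak numbers cannot be weighed. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no peak list here.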

Other observations

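The test of minimum widths, the X share in lists of equal length, the X share of the weaker peaks and the comparison of the highest autosomal peaks below were chosen after the lists had been seen. The first peak of the X began at position 1 in all 3 lists, with scores of 158.71 in replicate 1, 97.42 in replicate 2 and 7.88 in the series-level list. Peaks at position 1 were not particular to the X: replicate 1 also had them on chromosomes I, II, IV and V, and the series-level list on chromosomes I (score 20.06) and V (score 5.47). Replicate 2 had none on an autosome. The widest peak of replicate 1 was autosomal, on chromosome I at 15060199 to 15071355, with a score of 1358.17, and no replicate 2 peak overlapped it. The widest series-level peak lay in the same region, at 15060265 to 15071340, with a score of 19.87. Of the 10 highest-scoring autosomal peaks of replicate 1, 1 overlapped a replicate 2 peak, while 9 of the 10 highest of replicate 2 overlapped a replicate 1 peak (Fisher's exact test, two-sided, p = 0.00109). This test takes peaks as independent, although those of replicate 1 include neighbours on chromosome V, at 17119898 to 17126680 and 17128087 to 17132176. Over all autosomal peaks the matched shares were 23.7% in replicate 1 and 38.8% in replicate 2. The highest of replicate 1 lay on chromosome III at 1017274 to 1020667 (score 1459.71, rank 38 after 37 X peaks). The highest of replicate 2 lay on chromosome III at 7443761 to 7448823 (score 1946.66, rank 70 after 69 X peaks).

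The 50 highest-scoring replicated X peaks, with series-level scores of at least 135.45, were compared with the rest of the X. The hypothesis that X peaks outside the 50 are denser around them was not borne out: on average 9.74 such series-level peaks lay 1 to 10 kb away, inside the range of 8.06 to 10.1 from 1000 circular shifts. Nor did those neighbours score higher, with a median of 7.23 against a range of 6.30 to 7.84. Members of the 50 were left out as neighbours in both comparisons, so strong peaks next to each other are covered only by the distances below. The 50 peaks did not lie farther apart than other replicated X peaks either. Their median distance to the nearest other of the 50 was 39.5 kb, below the range of 72.1 to 183 kb from 10000 random draws of 50 among the 1094 replicated X peaks. A candidate explanation is that single strong regions were split into adjacent peaks, since 9 neighbouring pairs had edges within 10 kb. After joining such peaks, 41 regions remained, against a median of 48 in 1000 draws joined in the same way. The median distance was then 186.6 kb, inside the range of 85.7 to 198.3 kb from those draws. Joining removes the shortest distances and fewer regions lie farther apart by number alone, so this comparison cannot decide about clustering. Clustering of strong sites as a biological pattern beyond 10 kb is therefore neither shown nor excluded here, and within 10 kb it was not separated from splitting.

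The replicates differed in peak width, and neither of 2 technical explanations could be decided from the lists. Joining of neighbouring peaks in replicate 2 predicts similar widths for peaks that cover a single series-level peak. These were still 3.29 times wider in replicate 2 (bootstrap 95% interval 3.17 to 3.40, medians 1598 bp and 486 bp). However, the narrowest replicate 2 peak, at 998 bp, already exceeds that median of 486 bp, so similar widths could not have been found. The comparison therefore does not decide about joining. A wider window or longer fragment length in the calling of replicate 2 stays open as well. On the autosomes the narrowest 5% of peaks ended at 1345 bp in replicate 2 and 228 bp in replicate 1, a ratio of 5.91 (interval 5.53 to 6.22), but the narrowest replicate 2 peak of 998 bp already exceeds the replicate 1 median, so this ratio restates the pattern and does not test its cause. Both libraries belong to the same group, so no biological explanation was tested.

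A larger share of peaks lay on the X in replicate 2 than in replicate 1 (odds ratio 3.64, Fisher's exact test, two-sided, p = 2.43e-30, peaks taken as independent). The longer list of replicate 2 would be the cause only if its weaker peaks raised the X share, and the tables argue against this: its 1463 highest-scoring peaks were 98.2% on the X, against 84.4% in replicate 1, and the 1208 weaker peaks 91.6% (Fisher's exact test against those 1463, two-sided, p = 1.10e-15). By base pairs covered the odds ratio was 10.4, but X peaks were narrower than autosomal peaks in replicate 1 and wider in replicate 2, so this value does not decide about separate counting of narrow peaks. With peaks within 500 bp merged the X share was 84.9% in replicate 1, with a Wilson 95% interval of 82.87% to 86.70%. In replicate 2 it was then 94.1%, with an interval of 92.98% to 94.99%. These values argue against separate counting of peaks within 500 bp as the cause of the whole difference. Peaks separated by longer gaps were not merged, so separate counting over such gaps stays open. Differences in depth, in enrichment or in the control used for calling also stay open, since peak lists cannot test them. The design names no biological difference between the replicates.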
